A study of Arabidopsis thaliana with 33 samples.

How the data were processed

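RNA-seq was made from 15 samples (5 genotypes with 3 replicates each) and H3ac ChIP-seq from 9 ChIP and 9 input samples (3 genotypes with 3 replicates each), 33 samples in all, grouped by the genotype and assay in their labels. The 13 processed tables hold 1 value per genotype and none per replicate, so calls of genes, TEs and peaks rest on the authors' tests unless stated otherwise. Tests of overlaps, lists, centred folds and differences between mutants were made here on those values. The number of replicates behind a value is not recorded in the tables. The labels do not say whether replicates came from separate growths of seedlings, so p-values may measure only the spread between these samples. Values of the input libraries were not analysed here. The number of columns of per-sample values left unused was 0.

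Per the submitters' processing notes, which give no roles, the tools were CASAVA, TopHat2 2.0.12, Cufflinks 2.2.1, Cuffdiff, Bowtie2 2.4.1, MACS2 2.1.1.20160309, DiffBind and bedtools, with the build TAIR10. Settings, the counting of reads shared between copies and the use of strand are not given in the sources used here, so values of overlapping genes, close paralogs and TE copies are uncertain. The RNA tables hold an FPKM for each genotype, scaled by the authors between the 2 genotypes of a table, with the column layout of Cuffdiff per the file headers. Each deposited RNA table also holds a p-value and a q-value (adjusted p), and recomputation showed that the q-value is the Benjamini-Hochberg adjustment over the genes or TEs that the table marks as tested. The deposited test statistic, a score of the authors' test, has the opposite sign to the log2 change and served here only to derive standard errors. Each of the 4 gene tables lists 32823 genes, and 31189 TEs stand in each of the 4 for TEs. Because tables were scaled separately, FPKM values were tested within a table only, and what was compared across tables were the calls and log2 changes against WT of each table. WT gene values differed between tables by a near constant factor (medians of 0.998, 1.00 and 0.981 of the hhp1 table for mbd124, sant1234-null and hda6), and WT TE values by 0.987, 0.979 and 0.694. The ChIP gene tables of 32833 genes hold a raw read count, gene length, mapped reads and RPKM per genotype, and recomputation showed that the authors' RPKM is the count over length and mapped reads with no input subtracted. The peak tables hold log2 concentrations, a log2 fold of mutant over WT and an FDR deposited by the authors in the layout of DiffBind, per the file headers. Starts of genes and TEs count from 0 in the tables and were raised by 1.

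Depth can be read from the ChIP tables only, and that of the RNA libraries is unknown. The smallest adjusted p of the gene tables was 0.00192 for hhp1, 0.000861 for mbd124, 0.000723 for sant1234-null and 0.000899 for hda6, which many genes share. The smallest absolute log2 changes called were 0.408, 0.405, 0.407 and 0.440, and no smaller change was called.

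Genes and TEs were called at an adjusted p under 0.05 among those marked as tested, and peaks at an FDR under 0.05. Log2 changes were recomputed from FPKM without a pseudocount, and no fold is given against a genotype listed at 0, since such a value can be a failed estimate. Standard errors of log2 changes were taken from the change and the deposited statistic, scaled by the ratio of the normal quantile of p to the statistic (1.74). Peaks with centred folds were called again here by a normal test with the Benjamini-Hochberg adjustment. Its standard errors came from the deposited fold and p, or were the median one where these gave none. Overlaps of calls used Fisher's exact test, two-sided, on genes tested in both tables, beside the overlap of independent lists and 20 simulations of unchanged mutants against the shared WT with standard errors up to 1, from which correlations and covariances were taken. The simulations assumed a WT variance equal to the mutant's own, taken at the smaller of the 2 standard errors, and did not estimate it. Overlaps of peaks with genes or TEs needed 1 bp. H3ac against RNA used the log2 ratio of RPKM + 1, which understates the change of genes with few reads, and signal deciles split peaks or genes into 10 groups by mean signal. Genes were not independent replicates in any of these tests.

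A total of 14 gene lists with 153 genes was written before the data were examined: complex loci, floral repressors, floral promoters, DNA methylation and silencing, silenced reporters, histone deacetylases, jasmonate and salicylate defence, abscisic acid and cold, heat shock, circadian clock, leaf photosynthesis, root markers, floral organ identity and seed maturation. Each list's median was set against 10000 random lists of the same size matched on expression, as a description of these libraries. Lists of aliphatic glucosinolate, rapid-response, plastid and mitochondrial genes were added after the data were seen. Genes were named by a rule fixed in advance: every complex locus, the 8 largest log2 changes per direction among called genes with at least 5 FPKM in the higher genotype and above 0 in both, up to 4 called members per list with the smallest adjusted p, the 4 largest TE changes and peak folds per direction (TEs with at least 1 FPKM), and the 6 genes higher in both RNA and H3ac with the largest RNA change. Other genes named were chosen after their values were seen, which holds for the further list members, the TEs outside the largest and the genes named as shared. Symbols came from the tables or, for 23 symbols that a spreadsheet had turned into dates, from the reference TAIR10.1. Of the gene identifiers, 99.1% (32538 of 32823) were found there, and 71.7% of those (23335) had an identical start and end, so coordinates are those of the tables and the exon classes of peaks those of the reference.

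The functions for list tests, overlaps and shared controls were tested on simulated data with 200 changed genes, drawn from the standard errors of each table. At a planted log2 change of 0.5, 19% of changed genes were recovered for hhp1 (20431 genes), 18.5% for mbd124 (20322), 15% for sant1234-null (20631) and 8% for hda6 (20504). At a log2 change of 1 these were 82%, 81%, 80.5% and 79%, with 8 unchanged genes called in each, against 1 at the smaller change. These percentages are of a normal test on the simulated changes. Each deposited table called more than 200 genes, which loosens the adjusted threshold, so they are not the recovery of the authors' test.

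The design fixed in advance had a limma test of H3ac per gene over the 9 ChIP libraries, for each mutant against WT and between the mutants. With 1 value per genotype it could not be run, and H3ac per gene is given as values with no test. The overlap of H3ac changes between mutants therefore used genes with called peaks, a choice made after the data were seen, and camera and fry were not run on the H3ac lists for the same reason. Alternatives tried were an adjusted p or FDR of 0.01, an absolute log2 change of at least 1, at least 1 FPKM, a covered share of the peak of at least 0.5, H3ac from the peak table, and, added after the data were seen, TEs outside genes, genes outside TEs, centred peak folds, peaks at TEs outside genes, odds ratios within signal deciles, a pseudocount of 0.1 and centred RPKM ratios. Software used here was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.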

Results

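The series measured RNA and histone H3 acetylation (H3ac) in 12-day-old *Arabidopsis thaliana* seedlings of the wild type Col-0 (WT) and of mutants of a protein complex that, from the series title, contains the histone deacetylase HDA6 and a domesticated Harbinger transposase. RNA-seq covered 5 genotypes with 3 replicates each: WT, hhp1, a triple mutant of the methyl-CpG-binding-domain genes MBD1, MBD2 and MBD4 (mbd124), sant1234-null and hda6. ChIP-seq with an antibody against acetylated H3 covered WT, sant1234-null and hda6, again with 3 replicates each, and 9 input libraries were sequenced beside the 9 ChIP libraries. The question set by the design was which genes and transposable elements (TEs) change their RNA in each mutant, how far the mutants share those changes, and where H3ac differs. Each table held 1 value per genotype, so no value below has a replicate spread. Calls are those of the authors' tests, Cuffdiff for RNA and DiffBind for H3ac peaks, unless stated otherwise. Tests of overlaps, lists and differences between mutants were made here on these values. The RNA tables gave no depth. Summed over genes, the ChIP tables counted 69959151 reads for WT, 78316244 for sant1234-null and 68093284 for hda6. These sums equal 99.8%, 97.8% and 96.2% of the mapped reads. A read in overlapping genes may be counted more than once, so they need not be the share of reads in genes.

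In the libraries labelled mbd124, MBD2 fell from 17.5 to 6.45 FPKM in the authors' deposited table (log2 change -1.44, adjusted p 0.000861). The authors' deposited table listed MBD1 at 15.5 FPKM in WT and 0.0476 in mbd124 (adjusted p 0.619), and MBD4 at 21.8 and 0.208 (adjusted p 0.177), so neither passed the test. The labels do not say which loci carry the sant1234 mutations, and the loci of the SANT family were therefore followed by identifier. In the authors' deposited table of sant1234-null, AT1G09040 was listed at 1.75 FPKM in WT and 0.0181 in the mutant (adjusted p 0.117) and AT2G47820 at 1.28 and 0.532 (adjusted p 0.108). AT1G09050, which lies beside AT1G09040 on chromosome 1, was listed at 2.09 and 4.20 FPKM (adjusted p 0.183) in the authors' deposited table, and AT1G55050 was not tested. HDA6 (AT5G63110, chromosome 5, 25314104 to 25318347) was listed at 17.0 FPKM in WT and 18.8 in hda6 in the authors' deposited table (adjusted p 0.735), so its RNA was not lower in the libraries labelled hda6. AT5G12010, the Harbinger-derived locus followed here for hhp1, was listed at 11.7 FPKM in WT and 10.2 in hhp1 in the authors' deposited table (adjusted p 0.592), and its RNA gave no check of that label either. The labels do not say that this locus is the one mutated in hhp1. They name no alleles, and an allele can leave RNA in place. Among the 9 loci of this list, AT1G55050 rose in hhp1 (log2 change 3.28) and in hda6 (2.99), AT1G09040 rose in hhp1 (0.73) and hda6 (0.80), and MBD4 rose in hhp1 (0.48), each from the authors' deposited table. These made 3 higher and 0 lower of 9 measured loci in hhp1, 0 and 1 of 8 in mbd124, 0 and 0 of 8 in sant1234-null, and 2 and 0 of 9 in hda6. Adjusted over the list alone, the counts were 3 and 0, 0 and 1, 0 and 0, and 3 and 0.

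PCR1, a plant cadmium resistance protein, rose in the libraries labelled hhp1 from 2.49 to 15.8 FPKM in the authors' deposited table (log2 change 2.66). QQS, an orphan gene that affects starch content, rose from 4.16 to 19.1 FPKM and WRKY53, a senescence transcription factor, from 5.52 to 21.2 in the authors' deposited table. BGL2 (PR2), a glucanase induced by salicylate, rose from 10.9 to 35.4 FPKM, the defence regulator WRKY40 from 16.5 to 47.9 and the small heat shock gene HSP17.6C from 2.39 to 7.87 in the authors' deposited table. The lipid kinase gene PI4KG3 (AT5G24240, chromosome 5, 8228829 to 8234150) fell from 10.6 to 0.455 FPKM in the authors' deposited table (log2 change -4.54). CYP79F1 and MAM1, which act in the synthesis of methionine-derived glucosinolates, fell from 7.84 to 0.363 and from 49.4 to 5.62 FPKM in the authors' deposited table, and the jasmonate-induced defensin gene PDF1.2A from 5.58 to 0.408. AT5G41750 and AT5G37970 completed the 8 largest rises (log2 changes 1.70 and 1.62), and AT4G27654, PER52, GRXC11 and AT3G52535 the 8 largest falls (-2.84, -2.12, -2.10 and -2.07), in the authors' deposited table. Adjusted p was 0.00192, the smallest in the authors' deposited table, for each of these genes except PDF1.2A (0.0192) and AT3G52535 (0.0489). In all, 608 genes were higher and 688 lower among 21097 tested, 6.14% of them, and 136 of the higher and 147 of the lower had an absolute log2 change of at least 1.

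Of the lists fixed before the data were examined, the jasmonate and salicylate defence list had 4 members higher and 1 lower of 11 measured in the libraries labelled hhp1 (5 and 2 adjusted over the list alone). PR1 (log2 change 1.22), PR2 (1.70) and PR5 (1.11), markers of salicylate signalling, and VSP2 (0.54), a vegetative storage protein induced by jasmonate, rose in the authors' deposited table. The median of this list was 0.37, at percentile 99.97 of 10000 random lists matched on expression. In mbd124 it was -0.31 (percentile 0.62), in sant1234-null 0.49 (99.95) and in hda6 -0.07 (19.15). Among leaf photosynthesis genes 0 were higher and 3 lower of 18 (0 and 3 adjusted over the list alone). These were the Rubisco small subunits RBCS1B (-0.68) and RBCS2B (-0.60) and the carbonic anhydrase CA1 (-0.72) in the authors' deposited table, and the median of the list lay at percentile 0.05. It was also low in mbd124, sant1234-null and hda6, at percentiles 0.46, 0.25 and 0.13. Transcripts of plastid genes, a group examined after the data were seen, had 0 members higher and 22 lower of 52 in the same table. The floral repressor FLC rose from 1.42 to 3.04 FPKM in the authors' deposited table (log2 change 1.10, adjusted p 0.0351), as the 1 called member of 15 repressors (1 and 0 adjusted over the list alone). SPL4 (0.66) was the 1 floral promoter higher of 11 in the authors' deposited table (1 and 1 adjusted over the list alone). RD29B (1.21) and COR15A (0.77), genes induced by abscisic acid and cold, rose in the authors' deposited table, which made 2 higher and 0 lower of 10 (2 and 1 adjusted over the list alone). HSP17.6A (1.48), the floral organ gene PI (1.56) and the root hair gene LRX1 (-0.68) were the 1 member each called of 5 heat shock, 2 floral organ and 10 root genes in the authors' deposited table. Adjusted over the list alone these 3 lists had 2 and 0, 1 and 0, and 0 and 1 members higher and lower. No member was called among 19 genes of DNA methylation and silencing, 11 histone deacetylase genes or 9 clock genes, over all genes or adjusted over the list alone. No seed maturation gene and neither of the silenced reporter genes SDC and FWA was tested.

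ERF053 (AT2G20880, chromosome 2, 8985959 to 8987302), an AP2/ERF transcription factor, rose in the libraries labelled mbd124 from 0.261 to 14.9 FPKM in the authors' deposited table (log2 change 5.84). AIP1 (AT1G07430), a protein phosphatase 2C, rose from 0.356 to 8.92 and the glycosyltransferase gene UGT74E1 from 2.51 to 34.6 FPKM in the authors' deposited table. EXL1 and EXO, genes of the exordium family linked to brassinosteroid growth, fell from 130.3 to 3.31 and from 542 to 19.3 FPKM in the authors' deposited table. XTH22 (TCH4), a touch-induced xyloglucan endotransglucosylase, fell from 767 to 24.6 FPKM (log2 change -4.97) in the authors' deposited table. The transcription factor genes ERF054, ERF061 and PRE1, the ubiquitin ligase gene PUB19 and AT1G24580 rose by log2 changes of 4.24, 3.93, 3.84, 3.94 and 3.79 in the authors' deposited table. ERF012 (-4.08), AT4G27654 (-3.99), ERF022 (-3.96), TIFY 5B of the jasmonate ZIM-domain family (-3.81) and AT3G19680 (-3.79) completed the falls in the authors' deposited table. Every gene in this group had the smallest adjusted p of the authors' deposited table, 0.000861, except AT1G24580 (0.00236). Altogether 1020 genes were higher and 1350 lower among 21031 tested (11.3%), with 311 and 422 at an absolute log2 change of at least 1.

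The abscisic acid and cold list had 3 members higher and 2 lower of 10 in the libraries labelled mbd124 (4 and 2 adjusted over the list alone). RD29A (log2 change 1.30), the phosphatase ABI1 (1.33) and the transcription factor ABI5 (0.69) rose, and COR15A (-0.63) and KIN1 (-1.06) fell, in the authors' deposited table. The heat shock list had 0 members higher and 3 lower of 5 (0 and 4 adjusted over the list alone). These were HSFA2 (-1.51), HSP101 (-0.90) and HSP70 (-0.59) in the authors' deposited table. Jasmonate-responsive genes PDF1.2 (-1.78), LOX2 (-1.34), VSP1 (-0.94) and VSP2 (-0.81) fell while PR1 (1.09) rose in the authors' deposited table, giving 1 higher and 4 lower of 10 (1 and 4 adjusted over the list alone). Among floral repressors FLC rose (1.31), and TEM1 and TEM2, repressors of FT, fell from 83.5 to 18.6 and from 172.6 to 48.0 FPKM in the authors' deposited table. That made 1 higher and 2 lower of 15 (1 and 3 adjusted over the list alone). The promoter FUL fell (-1.03) in the authors' deposited table, 1 lower of 11 promoters in both counts, those over all genes and those adjusted over the list alone. The antenna protein genes CAB2 (-0.80), LHCB2.1 (-0.77) and LHCB2.2 (-0.71) fell in the authors' deposited table, 0 higher and 3 lower of 18 photosynthesis genes (0 and 4 adjusted over the list alone). The clock gene CCA1 (-0.76), LRX1 (-0.47) and the seed storage gene CRA1 (0.409 to 2.15 FPKM) were the 1 member each called of 9 clock, 10 root and 1 seed genes in the authors' deposited table. Adjusted over the list alone these lists had 0 and 2, 0 and 1, and 1 and 0 members higher and lower. None of 19 DNA methylation and silencing genes, 11 deacetylase genes or 2 floral organ genes was called over all genes or adjusted over the list alone, and SDC and FWA were not tested.

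The 8 largest rises in the libraries labelled sant1234-null were of genes listed below 1 FPKM in WT. AGO5 (AT2G27880, chromosome 2, 11871378 to 11876989), an argonaute protein known from germ cells, rose from 0.0171 to 7.27 FPKM in the authors' deposited table (log2 change 8.73, adjusted p 0.0217). AT1G56060 rose from 0.612 to 108 FPKM, GGP5, a gamma-glutamyl peptidase, from 0.0946 to 15.3 and TET9, a tetraspanin, from 0.290 to 15.9 in the authors' deposited table, with adjusted p of 0.0402, 0.0217 and 0.00692. AT5G54095 (log2 change 6.25), AT3G42850 (6.02), AT5G66150 (5.52) and SKS2 (5.31) also rose in the authors' deposited table. EXO fell from 545 to 39.5 FPKM, XTH22 from 769.9 to 86.3 and PI4KG3 from 10.6 to 0.918 in the authors' deposited table. AT2G37030 (-3.86), AT3G19680 (-3.26), ERF012 (-3.12), TIFY 5B (-3.04) and AT4G27654 (-2.98) were the other genes among the 8 largest falls in the authors' deposited table. The 8 falls had the smallest adjusted p there, 0.000723, except AT2G37030 (0.00196). In total 2001 genes were higher and 1271 lower among 21439 tested (15.3%), with 910 and 271 at an absolute log2 change of at least 1, and 23 of the higher genes were listed at 0 in WT.

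The flowering repressor FLC and its relatives MAF4 and MAF5 rose in the libraries labelled sant1234-null. FLC rose from 1.42 to 4.85 FPKM, MAF4 from 1.39 to 10.5 and MAF5 from 3.16 to 39.9 in the authors' deposited table (log2 changes 1.77, 2.92 and 3.66). The repressors TEM1 (-1.65), TEM2 (-1.12), SNZ (-0.63) and SVP (-0.44) fell in the authors' deposited table, so that 3 were higher and 4 lower of 15, and the same counts held adjusted over the list alone. The promoters FUL (-1.02), SPL3 (-0.66) and SOC1 (-0.53) fell in the authors' deposited table, 0 higher and 3 lower of 11 in both counts, over all genes and adjusted over the list alone. The median of the promoters was -0.53, at percentile 0.03 of matched lists. The defence list had 5 higher and 2 lower of 11, over all genes and adjusted over the list alone. PR5 (1.49), PR2 (1.43), PR1 (1.36), JAZ10 (0.55) and JAZ1 (0.49) rose, and PDF1.2 (-1.40) and LOX2 (-0.60) fell, in the authors' deposited table. HDA18, a deacetylase gene patterning the root epidermis, rose from 0.340 to 2.17 FPKM in the authors' deposited table (log2 change 2.67), the 1 call among 13 deacetylase genes in either count, over all genes or adjusted over the list alone. ROS1, a DNA demethylase (0.44), and NRPE1, the largest subunit of RNA polymerase V (0.46), rose in the authors' deposited table among 19 DNA methylation and silencing genes, but 0 passed adjusted over the list alone. RD29B rose (1.99) and KIN1 (-1.20) and ABI2 (-0.74) fell of 10 abscisic acid and cold genes in the authors' deposited table (1 higher and 3 lower adjusted over the list alone). HSP18.2 rose (0.70) and HSFA2 (-1.43) and HSP101 (-1.21) fell of 5 heat shock genes in the authors' deposited table (1 and 3 adjusted over the list alone). CAB2 (-0.82), LHCB2.2 (-0.63) and LHCB2.1 (-0.61) fell of 18 photosynthesis genes in the authors' deposited table (0 and 3 adjusted over the list alone). The 1 member called in each of the clock, root and floral organ lists was CCA1 (-0.51) of 9, IRT1 (0.97), the root iron transporter, of 10 and PI (2.47) of 2 in the authors' deposited table, with the same counts adjusted over the list alone. No seed maturation gene or silenced reporter gene was tested.

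In the libraries labelled hda6, AT3G29633 (chromosome 3, 11452509 to 11453528) rose from 0.140 to 34.6 FPKM in the authors' deposited table (log2 change 7.95, adjusted p 0.0159). QQS rose from 4.08 to 139 FPKM, PCR1 from 2.45 to 113, AT5G26270 from 3.78 to 169 and the non-coding gene AT1G67105 from 19.8 to 549.7 in the authors' deposited table, each with adjusted p 0.000899, the smallest there. AT5G45095 (log2 change 6.57), AT1G56060 (5.74, adjusted p 0.0220) and the U-box gene PUB54 (4.66) completed the 8 largest rises in the authors' deposited table. AT4G27654 fell from 31.0 to 2.04 FPKM, AT2G05510 from 52.4 to 7.24 and EXO from 533 to 142 in the authors' deposited table, and TIFY 5B (-2.96), ERF012 (-2.27), AT3G19680 (-2.08), AT5G19190 (-1.90) and AT4G27652 (-1.89) were the other large falls. In all 1556 genes were higher and 1028 lower among 21450 tested (12.0%), with 784 and 203 at an absolute log2 change of at least 1. Of the higher genes, 100 were listed at 0 in WT.

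The salicylate markers PR2, PR5 and PR1 rose from 10.7 to 198 FPKM, from 3.96 to 47.9 and from 8.70 to 86.4 in the libraries labelled hda6 (the authors' deposited table, log2 changes 4.21, 3.60 and 3.31). The jasmonate-responsive VSP2 (-1.84), VSP1 (-1.40) and LOX2 (-1.37) fell in the authors' deposited table, which gave 3 higher and 3 lower of 10 defence genes, over all genes and adjusted over the list alone. FLC rose from 1.39 to 5.11 FPKM, MAF4 from 1.36 to 9.63 and MAF5 from 3.09 to 15.7, while SNZ (-0.74), TEM1 (-0.73) and SVP (-0.52) fell, in the authors' deposited table. That gave 3 higher and 3 lower of 15 repressors (3 and 4 adjusted over the list alone). The promoters FUL (-1.49), SOC1 (-0.98) and SPL3 (-0.90) fell in the authors' deposited table, 0 higher and 3 lower of 11 in both counts, over all genes and adjusted over the list alone, and the list's median of -0.49 lay at percentile 0.01. The florigen gene FT and its activator CO did not pass the test in any mutant, and in hda6 the authors' deposited table listed FT at 0.978 FPKM in WT and 0.608 in the mutant (adjusted p 0.455). ROS1 fell from 12.0 to 4.69 FPKM in the authors' deposited table (log2 change -1.36), the 1 call among 19 DNA methylation and silencing genes in either count, over all genes or adjusted over the list alone. HDA18 rose (1.54) and HDA14 fell (-0.60) of 12 deacetylase genes in the authors' deposited table, with the same counts adjusted over the list alone. RD29B rose (1.74) and KIN1 (-1.38), COR15A (-0.98) and ABI2 (-0.86) fell of 10 abscisic acid and cold genes in the authors' deposited table, also 1 and 3 adjusted over the list alone. HSP17.6A (-1.22), HSFA2 (-0.98) and HSP101 (-0.76) fell of 5 heat shock genes in the authors' deposited table, 0 and 3 in both counts, over all genes and adjusted over the list alone. LHY rose (0.63) and PRR5 fell (-0.53) of 9 clock genes in the authors' deposited table (1 and 2 adjusted over the list alone). RBCS1B (-0.80) was the 1 photosynthesis gene lower of 18, and IRT1 (0.87) and RCI3 (0.56) the 2 root genes higher of 10, in the authors' deposited table, with the same counts adjusted over the list alone. SEP3 fell (-0.74) of 2 floral organ genes in the authors' deposited table (1 higher and 1 lower adjusted over the list alone). The seed regulator FUS3 (0.239 to 1.10 FPKM) and CRA1 (0.402 to 0.988) rose, 2 of 2 measured in either count, over all genes or adjusted over the list alone, in the authors' deposited table. SDC, a gene silenced by DNA methylation, was listed at 0 in WT and 7.95 FPKM in hda6 in the authors' deposited table without passing the test (adjusted p 0.405).

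**Figure D1:**
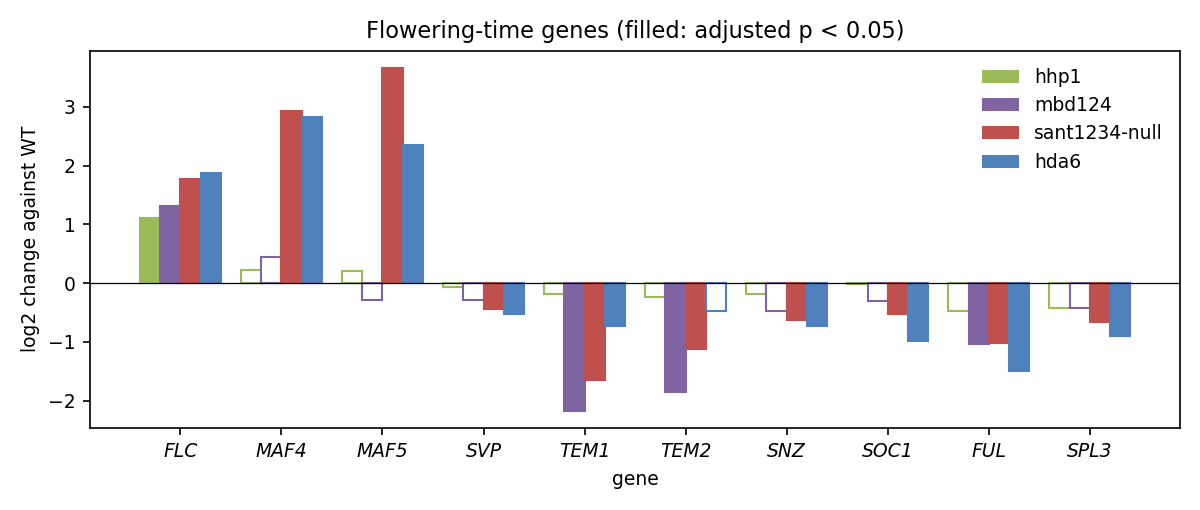
Log2 change against WT (vertical axis) of 10 flowering-time genes (horizontal axis) in the 4 mutants (colours), from the FPKM of the authors' deposited tables, with 1 value per genotype and no error bars. Filled bars passed the authors' test at an adjusted p under 0.05 and open bars did not: FLC was higher in every mutant (1.10, 1.31, 1.77 and 1.88), and MAF4 and MAF5 in sant1234-null and hda6.

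Calls of TE transcripts were most numerous in the libraries labelled hda6, with 168 TEs higher and 28 lower among 643 tested. AT1TE42875 (chromosome 1, 13127113 to 13128014), AT2TE23970 (chromosome 2, 5886322 to 5900126), AT1TE62360 (chromosome 1, 18806508 to 18807394) and AT3TE63935 (chromosome 3, 15812922 to 15814547) were each listed at 0 in WT in the authors' deposited table and overlapped no gene. The authors' deposited table listed them at 26046, 14755, 12147 and 6653 FPKM in hda6, each with adjusted p 0.000230. Of the 168 higher TEs, 119 were listed at 0 in WT and 135 overlapped no gene, as did 265 of the 643 tested. The largest falls were listed at 0 in hda6, led by AT1TE64710, at 10345 FPKM in WT in the authors' deposited table. In the other mutants 12 TEs were higher and 21 lower of 453 tested (hhp1), 14 and 20 of 449 (mbd124) and 27 and 20 of 472 (sant1234-null). In these, 8, 8 and 13 of the higher TEs overlapped a gene and 4, 6 and 14 did not. Of the TEs tested, 103, 107 and 119 overlapped no gene. AT5TE60280, which lies within AT5G41750 (chromosome 5, 16698234 to 16698950), rose in all 3: from 479 to 1173 FPKM in hhp1, from 473 to 1738 in mbd124 and from 467 to 13582 in sant1234-null in the authors' deposited tables. In sant1234-null AT2TE24530 (12.7 to 379 FPKM) and AT3TE30970 (126 to 1538) rose, and AT3TE17310 was listed at 0 in WT and 391 FPKM in the mutant, all outside genes in the authors' deposited table. In hhp1 AT3TE51150, which covers QQS, rose from 143 to 749 FPKM, AT5TE80015 from 424 to 1920.2 and AT5TE30315 was listed at 0 and 1341 in the authors' deposited table. AT2TE28020, outside genes, rose from 137 to 514 FPKM in mbd124, where AT1TE56695 and AT2TE11765 were listed at 0 in WT in the authors' deposited table. Falls included AT4TE46815 in hhp1 (log2 change -2.04), AT4TE34010 in mbd124 (-2.72) and AT2TE10740 in sant1234-null (-3.23) in the authors' deposited table. Over the 4 tables, 75 of 125 called TEs that overlapped a tested gene overlapped one called in the same direction. The TE tables carry their own scaling, which cannot be set beside the gene FPKM, with WT values in the hda6 table at a median of 0.694 of those in the hhp1 table.

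**Figure D2:**
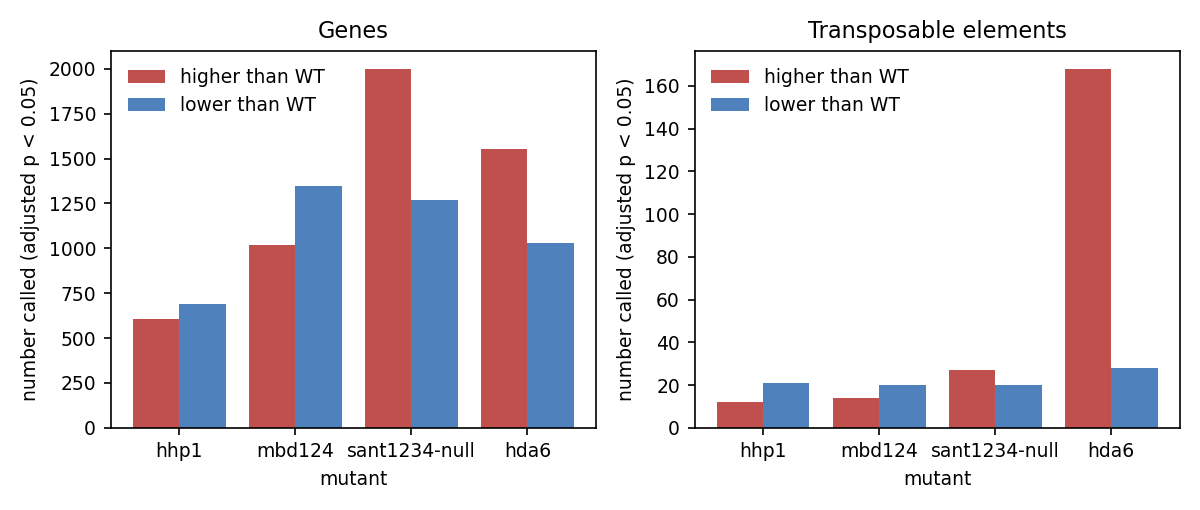
Number of genes (left) and TEs (right) that the authors' test called higher or lower than WT at an adjusted p under 0.05 (vertical axes) in each mutant (horizontal axes). The largest gene bar is the 2001 higher in sant1234-null and the largest TE bar the 168 higher in hda6.

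Mutants were then compared by the genes they shared. UGT74E1, FLC, PR1, WRKY53 and WRKY40 were among 122 genes higher in all 4 mutants, and EXO, XTH22, ERF012 and AT4G27654 among 175 lower in all 4, of 20775 genes tested in every table. Independent lists of these sizes would share 0.154 and 0.135 genes. Of 15 touch- and stress-induced genes listed after the data were seen, 6 were lower in all 4 mutants, XTH22 (TCH4) among them, and 3 higher. Genes higher in hda6 and in sant1234-null overlapped in 988 genes, where independent lists would share 129 (7.67 times), and those lower in 561, against 62.0 (9.05 times). The libraries labelled mbd124 shared 647 higher and 799 lower genes with sant1234-null, against 87.2 and 82.1 expected of independent lists (7.42 and 9.73 times). Libraries labelled hhp1 shared 368 higher and 396 lower genes with sant1234-null, against 52.3 and 41.7 (7.04 and 9.49 times; Fisher's exact test, two-sided, p 3.09e-241 for the higher genes). In these 3 pairs 26, 30 and 34 genes were called in opposite directions, and in the pairs without sant1234-null 89 (hhp1 and mbd124), 51 (hhp1 and hda6) and 60 (mbd124 and hda6). For the pairs without sant1234-null, the shared higher and lower genes numbered 178 and 365 (hhp1 and mbd124), 297 and 239 (hhp1 and hda6) and 440 and 525 (mbd124 and hda6), against 28.3 and 44.5, 39.5 and 33.8, and 65.1 and 66.5 expected.

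All of these comparisons used the same WT libraries. Unchanged mutants simulated against a shared WT gave correlations of 0.461 (hda6 with sant1234-null), 0.466 (mbd124 with sant1234-null) and 0.452 (hhp1 with sant1234-null), beside observed correlations of 0.740, 0.660 and 0.579. With no effect hardly any gene passes the test, so the 0 shared calls of the simulations are no reference for the overlaps above. The covariances of the log2 changes were 0.223, 0.165 and 0.112, beside simulated values of 0.0329, 0.0316 and 0.0295. For hhp1 with mbd124, hhp1 with hda6 and mbd124 with hda6 the correlations were 0.440, 0.465 and 0.497 beside simulated values of 0.460, 0.434 and 0.449, and the covariances 0.0722, 0.0848 and 0.117 beside 0.0294, 0.0286 and 0.0309. For hhp1 with mbd124 the correlation thus lay below its simulated value and the covariance above. These are correlations across genes, and genes are not independent replicates. The simulated values rest on an assumed WT variance, equal to the mutant's own at the smaller standard error. It was not estimated from the libraries, and a larger WT spread would raise the simulated correlations and covariances. Part of the overlaps in calls, and of any excess over independent lists, may come from the shared controls, which cannot be split because the tables hold no replicate values.

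The largest H3ac gains in both mutants were at sites listed at a concentration of 0 in WT. For sant1234-null, the peak on chromosome 3 at 10579065 to 10579465, over the TE AT3TE44000, had a concentration (log2 of normalised reads) of 0 in WT and 8.67 in the mutant in the authors' deposited table (FDR 2.48e-17). A peak in a coding exon of AT5G45520 (chromosome 5, 18450357 to 18450757) had 0 and 7.71 in the authors' deposited table. It also overlapped the TEs AT5TE66420 and AT5TE66425. The peaks at AT5TE54905 (chromosome 5, 15176195 to 15176595) and AT3TE37075 (chromosome 3, 8861268 to 8861668) reached 7.88 and 7.83 from 0 in the authors' deposited table. Lower peaks in sant1234-null lay at AT2TE09510 (chromosome 2, 2082224 to 2082624, from 6.98 to 0) and in a coding exon of MRD1 (log2 fold -4.33) in the authors' deposited table. Others lay in non-coding exons of AT2G05995 (-3.49) and APUM23 (-3.46) in the authors' deposited table. The MRD1 peak also overlapped AT1G07887, AT1G07893, HEI10 and RHM2, so it cannot be given to 1 gene. The AT2G05995 peak also overlapped the TEs AT2TE10735 and AT2TE10740. The largest gains in the libraries labelled hda6 lay at AT4TE32185 (chromosome 4, 7389720 to 7390120), in coding exons of AT5G26270 (chromosome 5, 9206434 to 9206834) and AT4G29200, and in a non-coding exon of AT2G01422. These had concentrations of 0 in WT and 9.70, 9.19, 8.95 and 8.65 in hda6 in the authors' deposited table. The AT5G26270 peak also overlapped an intron of AT5G04225. Coding exons of LSU3, a gene of the sulphur starvation response (5.64 to 0), and HIPP07 (5.45 to 0) were among the largest losses in the authors' deposited table, with 2 peaks outside genes and TEs. The tables give no read count at the sites themselves, and a concentration of 0 is reported here as listed.

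In sant1234-null 3802 peaks were higher and 3226 lower of 24998 (15.2% and 12.9%), and in hda6 1317 higher and 5613 lower of 24898 (5.29% and 22.5%). This split depended on size and centring. With an absolute log2 fold of at least 1 as well it was 2768 higher and 85 lower in sant1234-null and 804 and 372 in hda6. Centred folds were called by a normal test made here, not by the authors' test. With the median of all peaks set to 0 the hda6 split was 1997 higher and 844 lower, and with the median of each signal decile set to 0 it was 1544 and 212 in hda6 and 3480 and 389 in sant1234-null. The median log2 fold over all peaks was -0.02 in sant1234-null and -0.23 in hda6, and lower peaks are therefore lower on the authors' scale. In the decile of strongest peaks the median fold was -0.46 in sant1234-null and -0.55 in hda6, with 55.0% and 63.0% of peaks lower and 1.52% and 0.361% higher. Over the 3 weakest deciles the medians were 0.12, 0.24 and 0.28 in sant1234-null and 0.01, 0.06 and 0.07 in hda6, so the highest medians were not in the weakest decile. Genes listed at 0 FPKM in WT had a median of 7.59 RPKM in WT, 8.64 in sant1234-null and 9.35 in hda6, and the input libraries were not analysed here.

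**Figure D3:**
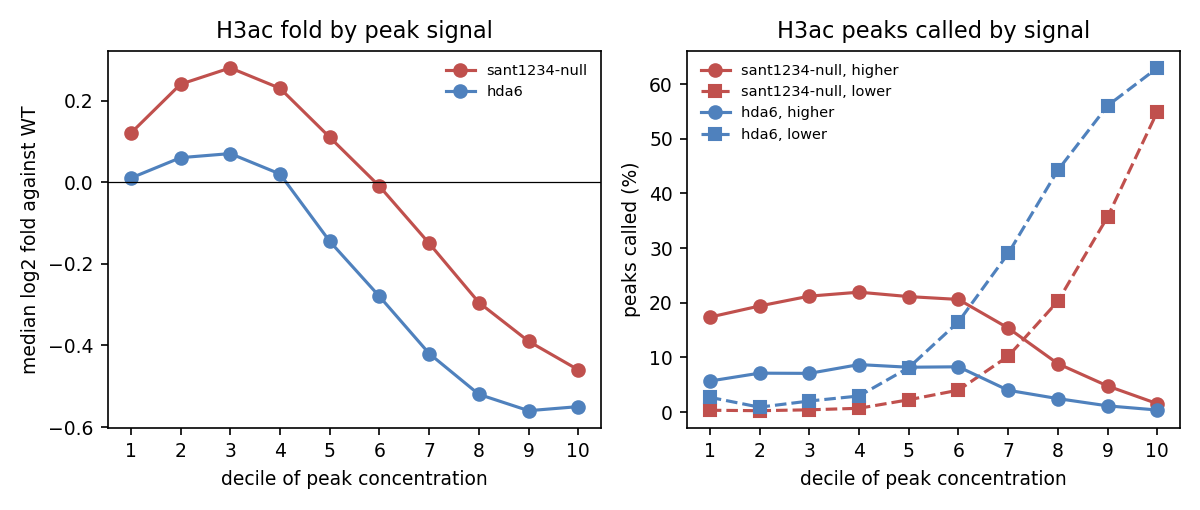
H3ac peaks by decile of mean concentration (horizontal axes, 1 weakest to 10 strongest), from the authors' deposited tables. Left, the median log2 fold against WT, which starts at 0.12 in sant1234-null and 0.01 in hda6, is highest in decile 3 (0.28 and 0.07) and ends at -0.46 and -0.55; right, the percentage of peaks called higher (circles) or lower (squares) at an FDR under 0.05, which reaches 55.0% and 63.0% lower in the strongest decile.

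TEs and genes were compared as sites of H3ac gain. Of the higher peaks in the libraries labelled hda6, 18.5% overlapped a TE against 7.79% of other peaks (odds ratio 2.68, Fisher's exact test, two-sided, p 2.17e-33, adjusted p 3.73e-33 over 12 tests), and the common odds ratio within signal deciles was 2.26. In sant1234-null the shares were 5.89% and 5.58% (odds ratio 1.06, p 0.445, adjusted p 0.445). Within signal deciles the common odds ratio in sant1234-null was 0.938 (Mantel-Haenszel test, p 0.392), and 0.956 (p 0.628) for TEs outside genes. Without deciles, the odds ratio was 1.23 (Fisher's exact test, p 0.0261) when TEs had to cover a share of at least 0.5 of the peak. Its value within deciles was not computed. Of all peaks, 95.1% in sant1234-null and 92.1% in hda6 overlapped a gene, as did 93.0% and 77.6% of the higher peaks. Genes with higher peaks and no lower ones numbered 3956 in sant1234-null and 1134 in hda6, and those with lower peaks and no higher ones 4215 and 7567. The mutants shared 890 genes with higher peaks, against 157 expected of independent lists (5.66 times), and 3668 with lower peaks, against 1507 (2.43 times), while 233 genes had peaks called in opposite directions. Over matched peaks the folds correlated at 0.823, beside 0.420 simulated for unchanged mutants against the shared WT, with a covariance of 0.268 beside 0.0272. Part of the excess may come from the shared controls here too, and the simulated values again rest on an assumed WT variance. Lower calls also gathered at the strongest peaks in both mutants. In sant1234-null and hda6, 55.0% and 63.0% of peaks were lower in the strongest decile, against 0.32% and 2.69% in the weakest. Independent lists therefore understate the overlap of lower peaks that signal alone would give. The overlap within signal deciles was not computed.

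H3ac over the loci followed in RNA went as follows, as RPKM, reads scaled to gene length and to the mapped reads of the library, which had no test. In sant1234-null the authors' deposited table gave AT1G09040 10.1 in WT and 3.97 in the mutant, AT1G09050 10.9 and 6.26, AT2G47820 12.9 and 23.4 and AT1G55050 6.80 and 19.2. The 1 peak in AT1G09040 was nonetheless called higher in the authors' deposited table (log2 fold 1.49), as was 1 of the 2 peaks in AT1G55050, while the peaks in AT1G09050 and AT2G47820 were not called. HDA6 had 20.4 RPKM in WT and 15.5 in each mutant, and AT5G12010 66.9 in WT, 45.7 in sant1234-null and 42.6 in hda6 in the authors' deposited table, both with lower peaks in each mutant. At the flowering repressors, peaks at MAF4 were higher in sant1234-null and hda6 (3.85 RPKM in WT, 7.25 and 6.54 in the mutants) and that at FLC in sant1234-null (4.71 and 6.63) in the authors' deposited table. TEM1 and TEM2 had lower peaks in sant1234-null, with 82.6 and 79.4 RPKM in WT and 57.8 and 53.5 in the mutant in the authors' deposited table. Of 14 repressors with a peak, 3 had higher and 3 lower ones in sant1234-null, and 1 higher and 3 lower in hda6. The median log2 ratio of RPKM + 1 over the repressors was -0.14 in sant1234-null and -0.15 in hda6, at percentiles 0.175 and 0.05 of lists matched on H3ac level, and that over photosynthesis genes -0.18 and -0.16, at percentiles 0.12 and 0.375. The medians of the other lists with such a value lay inside the interval of matched lists in both mutants. Peaks at PR5, PR2, PR1, LOX2 and THI2.1 made 5 higher and 0 lower of 10 defence genes in sant1234-null, and PR5 1 of 9 in hda6. SDC (7.74 and 16.9 RPKM) and FWA (6.38 and 9.61) both had higher peaks in sant1234-null in the authors' deposited table. Root genes had 5 higher and 0 lower of 8 in sant1234-null and 0 of 6 in hda6, among them RCI3 with 8.50 and 14.1 RPKM in the authors' deposited table. Photosynthesis genes had 0 higher and 3 lower of 17 in sant1234-null and 0 and 2 of 19 in hda6. In sant1234-null the numbers with higher and lower peaks were 3 and 2 of 9 complex loci, 2 and 1 of 7 floral promoters, 3 and 2 of 16 silencing genes, 3 and 1 of 11 deacetylase genes, 1 and 0 of 10 abscisic acid and cold genes, 1 and 0 of 5 heat shock genes, 1 and 1 of 8 clock genes, 0 and 0 of 1 floral organ gene and 3 and 0 of 5 seed genes. In hda6 they were 0 and 3 of 7, 0 and 0 of 7, 1 and 3 of 16, 1 and 5 of 10, 0 and 1 of 10, 0 and 0 of 4, 0 and 2 of 8, 0 floral organ genes with a peak, and 0 and 0 of 4.

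Genes that gained RNA gained H3ac more often than other genes. GGP5 (7.30 to 17.7 RPKM), AT5G54095 (12.2 to 36.9), TET9 (10.7 to 22.9), AT1G56060 (12.4 to 21.2), AGO5 (6.50 to 10.5) and AT3G42850 (6.35 to 8.46) had higher RNA and higher peaks in sant1234-null in the authors' deposited tables. For the libraries labelled hda6 the genes were AT5G26270 (8.50 to 45.3 RPKM), AT5G45095 (13.5 to 37.1), AT3G29633 (8.21 to 27.6), AT1G67105 (7.79 to 16.5), QQS (5.21 to 15.8) and AT1G56060 (12.4 to 15.3) in the authors' deposited tables. Higher peaks were found at 634 of 1728 genes with higher RNA in sant1234-null, 36.7% against 12.0% of other genes (odds ratio 4.25, Fisher's exact test, two-sided, p 3.27e-134, adjusted p 2.61e-133 over 8 tests). In hda6 they were found at 188 of 1256, where 44.4 were expected of independent lists, and at 2.68% of other genes (odds ratio 6.38, p 7.34e-70, adjusted p 1.96e-69 by the same exact test). Genes with lower RNA had lower peaks in 22.2% of cases in sant1234-null, against 20.8% of other genes (odds ratio 1.09, p 0.280, adjusted p 0.280), and in 22.7% in hda6, against 38.7% (odds ratio 0.464, adjusted p 1.40e-21). Within signal deciles the odds ratio for lower RNA with lower peaks in sant1234-null was 0.860 (p 0.0755). Genes with higher, lower and other peaks had median RNA changes of 0.24, -0.03 and -0.01 in sant1234-null and 0.39, 0.01 and 0.02 in hda6, on the log2 scale. Across all genes tested, the change in RNA and the log2 ratio of RPKM + 1 had Spearman's rho of 0.223 in sant1234-null (21280 genes) and 0.0717 in hda6 (21215 genes), a correlation across genes, which are not independent replicates. The hda6 value was 0.135 after the median of each signal decile was removed. None of these comparisons of RNA with H3ac was matched on WT expression. For all genes above 0 to 1 FPKM in WT, median RPKM was 8.40 in WT, 11.2 in sant1234-null and 10.6 in hda6. For those above 20 to 100 FPKM it was 15.1, 14.1 and 13.5. The excess of higher peaks at genes with higher RNA was therefore not separated from their WT expression.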

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

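The tests in this part were chosen after the results were seen, except those of read-through from neighbouring genes and of the scaling of the TE tables.

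Among the genes of the 14 lists fixed before the data were examined, 4 were called in opposite directions in a pair of mutants, which set them apart. Lists added later hold others, such as CBF1, which fell in hhp1 (log2 change -1.08) and rose in mbd124 (1.90) in the authors' deposited tables. Because they were picked for opposite calls, a test of the difference between the mutants restates those calls, and the differences are given as values without a p. VSP2, the jasmonate-induced storage protein gene, rose in hhp1 (log2 change 0.54) and fell in mbd124 (-0.81) and hda6 (-1.84) in the authors' deposited tables, with differences of 1.34 and 2.38. COR15A, a cold-induced chloroplast protein gene, rose in hhp1 (0.77) and fell in mbd124 (-0.63) and hda6 (-0.98) in the authors' deposited tables, with differences of 1.40 and 1.75. HSP17.6A, a small heat shock protein gene, rose in hhp1 (1.48) and fell in hda6 (-1.22) in the authors' deposited tables, a difference of 2.70. ROS1, the DNA demethylase gene, rose in sant1234-null (0.44) and fell in hda6 (-1.36) in the authors' deposited tables, a difference of 1.80. No replicate values stand behind these differences, and no explanation for them was tested.

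H3ac folds were lower at the strongest peaks than at the weakest in sant1234-null and hda6, with the highest medians in the third decile (0.28 and 0.07). A single scaling factor between libraries would shift all deciles alike, but the median log2 fold of the weakest decile lay above that of the strongest. The difference was 0.58 in sant1234-null (bootstrap interval 0.56 to 0.60) and 0.56 in hda6 (0.55 to 0.58). The bootstrap resampled peaks as if they were independent, so its intervals hold no spread between libraries. Under lower enrichment over background in the mutant libraries, genes with higher RNA would have the same ratio as genes of equal H3ac level. Their median log2 ratio exceeded that of genes matched on H3ac level by 0.28 in sant1234-null and 0.18 in hda6, above the intervals of matched lists. The lists were not matched on WT expression, so this comparison cannot decide against lower enrichment. All genes above 0 to 1 FPKM in WT had medians of 8.40 RPKM in WT, 11.2 in sant1234-null and 10.6 in hda6. For the losses at strong peaks lower enrichment stays open too: genes listed at 0 FPKM in WT had a median RPKM 1.14 times that of WT in sant1234-null and 1.23 times in hda6 (8581 genes). Either lower enrichment or a spread of acetylation to silent genes could give this, and the inputs were not analysed here. The loss of a deacetylase complex, the biological difference in the design, was not tested as an explanation. Its direct effect would be higher acetylation, so the losses at strong peaks ran the other way on the authors' scale.

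EXO, XTH22 and ERF012 were among the 175 genes lower in every mutant, all measured against the same WT libraries. A shift of the WT libraries alone would lower a gene equally in each mutant, but 90 of the 175 differed between the mutants (chi-square test over the 4 changes, treated as independent; again 90 with the median of each separately scaled table removed), which argues against it as the whole cause for these, while for the other 85 it cannot be told apart from a shared effect of the mutations. Handling at harvest may move touch- and stress-induced genes: of 15 rapid-response genes, 6 were lower in every mutant (TCH2, TCH4, ZAT12, ERF104, MYB44 and CBF2) and 3 higher (WRKY33, WRKY40 and WRKY53). The bound of this test was revised after the counts were seen, members went both ways, and the labels give no harvest batch, so handling cannot be told apart from genotype. A shared effect of the mutations on these genes stays open as the biological explanation.

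TE transcripts were called in genes as well as outside them, and the explanations differed. Reads of the overlapping gene are a candidate explanation for TEs in genes, since 75 of 125 called TEs with a tested gene overlapped a gene called in the same direction. In hda6 135 of the 168 higher TEs overlapped no gene, as did 14 of 27 in sant1234-null, which argues against gene reads for those. Read-through from a neighbour is argued against as the source of most of the 135, with 8 having a gene called higher within 1000 bp, and scaling of the TE table by a median log2 difference of -0.15 between a TE and its gene (quartiles -0.46 and 0.16, 256 pairs). Reads shared among TE copies were not tested, so release of these TEs in hda6 stays a hypothesis.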

How the results depend on the processing

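The choices of TEs outside genes, genes outside TEs, centred folds, changes or ratios, odds ratios within deciles, the smaller pseudocount and the overlap of genes with called peaks were made after seeing the data, and the others before the data were examined. No paired analysis was possible because the tables hold 1 value per genotype. For the same reason the following were not run: leaving out replicates, the replicate block and the pseudocounts for RNA genes and TEs, and, for limma on H3ac per gene and between hda6 and sant1234-null, the pseudocount, the filter on low values, the ratio to input, quantile normalisation, the fit of 6 libraries, the block, leaving out replicates and the stricter adjusted p. Other splits of the samples could not be made either.

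Of the alternative values of the comparisons, 58 kept their direction and call or stayed within 1.5 times in total, 20 moved further, 1 passed the threshold newly and 3 changed direction without passing it. These 3, within signal deciles in sant1234-null, were the odds ratio of TEs at higher peaks (1.06 to 0.938), the same for TEs outside genes (0.956, beside 1.16 without deciles) and that of lower RNA with lower peaks (1.09 to 0.860), and their cause was not tested. At an adjusted p of 0.01, 774 genes were called in hhp1 (1296 at 0.05) and 2162 in sant1234-null (3272), and 15, 19 and 27 TEs in hhp1, mbd124 and sant1234-null (33, 34 and 47). With an absolute log2 change of at least 1, genes numbered 283, 733, 1181 and 987 in hhp1, mbd124, sant1234-null and hda6 (1296, 2370, 3272 and 2584 without it). Peaks at an FDR of 0.01 numbered 4058 in sant1234-null and 3202 in hda6 (7028 and 6930 at 0.05), and with an absolute fold of at least 1, 2853 (2768 higher and 85 lower) and 1176 (804 and 372). These counts fall by construction, while the size filter turned the hda6 balance to mostly higher. Outside genes 7, 11 and 16 TEs were called in hhp1, mbd124 and sant1234-null. With the median fold set to 0, the normal test made here called 2841 peaks in hda6, and with decile medians set to 0, 3869 in sant1234-null and 1756 in hda6. Centring also turned the balance in hda6 from 1317 higher and 5613 lower to 1997 and 844, or 1544 and 212 by decile. The odds ratio of TEs at higher peaks in sant1234-null was 1.23 (Fisher's exact test, p 0.0261) with a share of at least 0.5 of the peak covered, and 1.06 (p 0.445) at 1 bp, with p from 0.0261 to 0.628 over the alternatives. The rho of RNA and H3ac in hda6 went from 0.0717 to 0.135 with decile medians removed. For the last of these, the TE share and the TEs outside genes, the cause was not tested. Calls of named genes and TEs and of called list members were counted once per mutant. Of these calls, 51 were lost at an adjusted p of 0.01 (152 were kept) and 53 at an absolute change of 1 (150 were kept). Entries without a log2 change, listed at 0 in 1 genotype, counted as kept at that size. The 16 named peaks kept their calls at an FDR of 0.01. The depth of the RNA libraries is unknown here, and no change below the smallest ones called passed the test.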

Other observations

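The tests in this part were all chosen after the results were seen. Genes of aliphatic glucosinolate synthesis, which make methionine-derived defence compounds, were lower in hhp1: 10 fell and 0 rose of 17. CYP79F1 (log2 change -4.43), MAM1 (-3.14), FMOGS-OX1 (-2.78), BCAT4 (-1.92) and the regulator MYB29 (-1.42) led the falls in the authors' deposited table, while MYB28 had a change of 0.32 and did not pass the test. The median of the list was -0.82, beside -0.13 to 0.12 for matched lists. The list holds CYP79F1 and MAM1, which had been seen among the largest falls in hhp1, so this comparison partly restates them. A median without them was not computed. In mbd124 6 fell and 0 rose (FMOGS-OX1 -2.01 and CYP79F1 -1.95 in the authors' deposited table, list median -0.41), in hda6 4 fell and 1 rose (CYP79F1 -1.30, median -0.14) and in sant1234-null 0 fell and 1 rose (SOT17 0.64, median -0.02). The difference between mutants was not tested.

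Transcripts of plastid genes were lower in hhp1, where 22 fell and 0 rose of 52. RBCL, the large Rubisco subunit, fell from 19.6 to 7.51 FPKM, PSBA, a photosystem II core protein, from 30.3 to 15.5 and PETB of the cytochrome complex by a log2 change of -1.96 in the authors' deposited table. The median was -1.06, beside -0.06 to 0.13 for matched lists. In the other mutants 6 rose and 0 fell of 51 (mbd124), 0 rose and 4 fell of 49 (sant1234-null) and 0 rose and 1 fell of 50 (hda6), with medians of 0.01, -0.51 and 0.01. That of sant1234-null also lay below its matched lists (-0.06 to 0.20). Mitochondrial genes had 0 higher and 3 lower of 16 in hhp1, 3 and 0 of 21 in mbd124, 0 and 0 of 18 in sant1234-null and 0 and 0 of 21 in hda6. Their medians were -0.84, 0.76, -0.30 and 0.50, below matched lists in hhp1 (-0.21 to 0.33) and sant1234-null (-0.14 to 0.62), above them in mbd124 (-0.22 to 0.24) and inside in hda6 (-0.11 to 0.54), so organelle transcripts shifted in more than 1 mutant and in both directions. The rapid-response list had 4 higher and 7 lower of 14 in hhp1, 5 and 8 of 15 in mbd124, 6 and 8 of 15 in sant1234-null and 5 and 6 of 14 in hda6. RNA selection is not given in the sources used here, and organelle transcripts may vary with it, so the plastid median of -1.06 does not separate a change in the seedlings from library preparation.

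The place of the genes higher in hda6 was a further question. Of these, 19.7% overlapped a TE, against 15.1% of other tested genes (odds ratio 1.37, Fisher's exact test, adjusted p 2.90e-05), and 12.9% lay in the 25 of 121 genome bins richest in TEs, against 6.51% (odds ratio 2.12, adjusted p 8.92e-17). In sant1234-null the odds ratios were 1.10 (adjusted p 0.303) and 1.04 (adjusted p 0.868). Genes lower in hda6 had odds ratios of 0.986 and 1.02, so the excess was seen for rises only. Genes listed at 0 in WT can be tested only where the mutant has reads. They made 100 of the higher genes in hda6 and 23 in sant1234-null, which may add to the excess. A greater response of genes in TE-rich chromatin in hda6 therefore stays a hypothesis, and the difference between the mutants was not tested.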
